A study of Rattus norvegicus with 12 samples.

How the data were processed

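RNA from 12 samples of rat aortic vascular smooth muscle cells was hybridised to Affymetrix Rat Gene 1.0 ST arrays, 3 each for untreated cells and for cells after 6, 12 and 24 h of 100 nM Ang II. Per the labels' protocols the cells were grown in 10% fetal bovine serum, kept without serum for 48 h, extracted with Trizol, and labelled with biotin from 100 ng of total RNA. The values used are the deposited log2 values, 1 per probe set and array, which the authors made with RMA and Partek per the submitters' processing notes. The versions of these tools, the background correction, the summary level and any filter are not given in the sources used here, and scanner files were not used here, so that scale and centring rest on the values alone. The array medians of the deposited log2 values were 7.22 to 7.32, and all values lay between 2.25 and 14.6. No sample was left out, and samples were grouped by their titles. For arrays no read depth exists, and the number of arrays limits the precision.

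The value table has 29214 rows. A table of the platform's annotation listed 15633 of these probe sets, 15310 with 1 gene symbol and 323 with several, and the other 13581 are unnamed here. Symbols were looked up in a RefSeq gene table of the rat assembly GRCr8, through the gene identifier for 14481 genes and through an accession for 1, while 24 kept the annotation's symbol, and 0 symbols changed. No coordinates are given because the files name no build. Probe sets with several symbols were not named. For the 527 genes with more than 1 probe set, the probe set with the highest mean over all 12 arrays was used, which left 14506 genes. In 319 rows all 12 values equalled those of another row.

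Genes were tested with limma 3.58.1 in R 4.3.3. A linear model with 4 group means was fitted to all 12 arrays, with 8 residual degrees of freedom and 3.37 prior degrees of freedom from eBayes. P-values were adjusted with the Benjamini-Hochberg method over all genes within each comparison, at a threshold of 0.05. Tests of single comparisons and of lists were two-sided. The F test and the counts over regroupings and splits of the arrays looked at the upper tail only. The comparisons were each of the 3 times with control, 12 h with 6 h and 24 h with 12 h, besides an F test over the 4 groups. A gene was called opposite when it passed at 6 h and at 24 h with different signs and the difference of these times passed too. No filter on dim genes was applied.

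Before the data were examined, 29 gene lists were fixed with 690 entries, of which 629 were measured (13 to 34 per list). They cover signalling, transcription factor, cell cycle, metabolic, contractile and matrix genes and markers of endothelial cells, leukocytes and fibroblasts. Lists were tested with camera from limma, with a preset inter-gene correlation of 0.01 and adjustment over the 87 tests of lists and times, and again with the correlation estimated from the data (statmod 1.5.0) and with fry. The named genes follow a rule set at the same time: in each comparison with control the 10 largest rises and the 10 largest falls among genes that passed and whose arrays were fully separated, up to 4 passing members of each list with the largest change, and the 3 Ang II receptor genes; between neighbouring times the 5 largest in each direction; and for opposite genes up to 5 in each direction.

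Steps were tested on simulated data first. For Ang II 24 h against control, with 50 genes at each fold among 14506, 58% of genes changed by 1.25-fold, 96% of those changed by 1.5-fold and 100% of those changed by 2-fold or 4-fold were recovered, with 8 unchanged genes called. With no change simulated at 6 h, 0 genes were called. The camera step returned 1 list for 1 shifted list. The simulated genes were independent of each other, whereas the estimated correlation within a list reached 0.343 in the data. The check therefore does not show how often the list test makes false calls with correlated genes.

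The alternatives were the 2 groups of a comparison alone, the replicate number as a block, leaving out each array, a filter at the median level, all probe sets, the mean of a gene's probe sets, a further quantile normalization, median centring, a trended and robust variance, no moderation, array weights, a minimum of 1.5-fold, and for lists the estimated correlation and fry. A fit without the array of narrowest spread in each Ang II group (Ang II 6 h replicate 2, 12 h replicate 1 and 24 h replicate 2) was added after the data were seen. Tables were prepared with Python 3.11.15 and pandas 2.3.3, and figures with matplotlib 3.10.9.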

Results

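Gene expression was measured in vascular smooth muscle cells from the aorta of Sprague-Dawley rats, the muscle cells of the vessel wall, after exposure to angiotensin II (Ang II), the peptide hormone of the renin-angiotensin system that constricts vessels. The cells were kept without serum for 48 h and received 100 nM Ang II. The 12 arrays (Affymetrix Rat Gene 1.0 ST) form 4 groups of 3: untreated cells as the control, and cells after 6 h, 12 h and 24 h of Ang II. The labels disagree on the times, because the treatment protocol names 1, 3 or 24 h, whereas the sample titles and the study design name 6, 12 and 24 h, which are used here. The labels call the 3 arrays of a group biological replicates without saying that they came from separate animals or cultures, so p-values measure the spread between these arrays. Untreated cells kept for 6, 12 or 24 h longer were not analysed here, so each comparison with control holds both Ang II and time in culture. The small number of arrays limits the precision, with a median standard error of a log2 difference of 0.0667.

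The arrays fell into their 4 groups. The correlation across genes was 0.9975 to 0.9984 between arrays of 1 group and 0.9868 to 0.9941 between arrays of different groups, where genes are not independent replicates. The first principal component held 42.9% of the variance and set the 6 h arrays apart from control, and the next component (25.1%) set the 24 h arrays apart from control. Of 14506 genes tested, 7465 differed among the 4 groups (limma F test, adjusted p under 0.05), and 7484 changed against control at 1 or more of the 3 times.

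**Figure D1:**
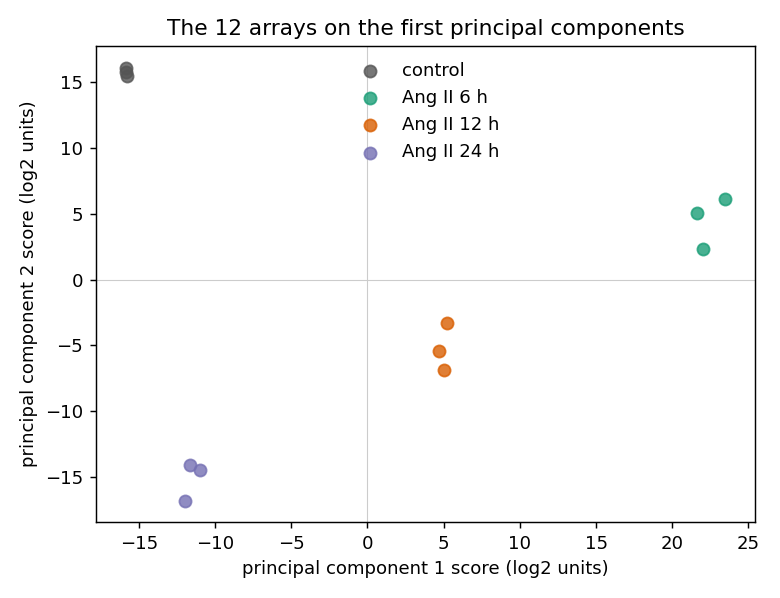
Scores of the 12 arrays on the first component (x axis) and on the next component (y axis), in log2 units, over all genes tested; each point is 1 array, coloured by group. The 3 arrays of each group lie together, with control near −15.8 and Ang II 6 h between 21.6 and 23.5 on the x axis.

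The comparison of Ang II 6 h with control asked which genes had changed early in the response. The largest rise was that of Olr1, the receptor for oxidised low-density lipoprotein, at 12.2-fold (log2 change 3.61 ± 0.12, SE, n = 3 per group, adjusted p = 1.48e-09). Next came the amino acid transporter gene Slc7a8 (10.9-fold, log2 change 3.45 ± 0.05) and the tissue plasminogen activator gene Plat (10.5-fold, 3.39 ± 0.07). Further rises were those of Fgl2 (3.34 ± 0.12), the interferon-responsive gene Usp18 (3.16 ± 0.21), Esm1 (2.96 ± 0.07), Tfpi2 (2.83 ± 0.12), C9h6orf141 (2.72 ± 0.06), Ramp3 (2.72 ± 0.12) and Ptprn (2.57 ± 0.06). Agtr1a (NCBI gene 24180), which encodes the main vascular receptor for Ang II, fell 5.93-fold (log2 change −2.57 ± 0.06, adjusted p = 7.19e-11). The other large falls were those of Ldb2 (−3.15 ± 0.13), the growth factor gene Fgf16 (−2.75 ± 0.10), Pi15 (−2.33 ± 0.13), Lpar4 (−2.31 ± 0.09), Zc3h6 (−2.23 ± 0.09), C1qtnf7 (−2.16 ± 0.08), Plpp3 (−2.14 ± 0.07), Sesn3 (−2.09 ± 0.06) and the adhesion molecule gene Vcam1 (−2.02 ± 0.10). These 20 genes were named among those whose 3 arrays of 1 group lie wholly above the 3 of the other, which was so in 47.2% of all genes at 6 h, against 10% by chance.

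In total 2703 genes were higher and 2488 lower at 6 h (limma, adjusted p under 0.05), of which 468 and 529 differed by at least 1.5-fold. Of the other receptor genes, Agtr1b had a log2 change of 0.16 ± 0.08 (adjusted p = 0.163) and Agtr2 of −0.08 ± 0.13 (adjusted p = 0.7). Among 29 gene lists fixed in advance, 12 passed camera, a test of whether a list moved relative to all other genes, 6 upwards and 6 downwards. With an estimated in place of a preset inter-gene correlation 0 lists passed (6 at an unadjusted p under 0.05). The fry test, which asks only whether a list's genes move on balance one way, passed 26.

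Immediate-early and AP-1 transcription factors, genes that respond to stimulation without new protein synthesis, were mostly lower 6 h after Ang II than in untreated cells: 3 of 23 rose and 17 fell (3 and 17 adjusted over the list alone). Their median of −0.53 had camera adjusted p = 1.07e-05, and adjusted p = 0.304 with an estimated correlation. Fosl1 went the other way and rose 5.1-fold (2.35 ± 0.06), while Fos (−1.85 ± 0.10), Egr3 (−1.79 ± 0.09) and Egr2 (−1.74 ± 0.08) fell. The feedback regulators of MAP kinase signalling were higher: 10 of 17 rose and 4 fell (10 and 5 adjusted over the list alone), led by the phosphatase genes Dusp6 (1.28 ± 0.07), Dusp10 (1.26 ± 0.07) and Dusp7 (1.00 ± 0.04). Their median of 0.40 had camera adjusted p = 0.0165, and adjusted p = 0.426 with an estimated correlation. All measured mitotic genes fell: 0 of 27 rose and 27 fell (0 and 27 adjusted over the list alone), with Ccnb1, the gene of a mitotic cyclin, at −0.83 ± 0.06 and Top2a at −0.70 ± 0.06. Their median of −0.55 had camera adjusted p = 3.3e-16, and adjusted p = 0.11 with an estimated correlation. Of the G1/S and DNA replication genes, 4 of 34 rose and 17 fell (5 and 17 adjusted over the list alone), with E2f1 at −0.61 ± 0.05 and Mcm7 at −0.50 ± 0.05. Their median of −0.20 had camera adjusted p = 0.000774, and adjusted p = 0.333 with an estimated correlation. The cell cycle inhibitors were lower too: 2 of 16 rose and 7 fell (3 and 7 adjusted over the list alone), among them Ccng2 (−1.25 ± 0.07) and Btg1 (−1.01 ± 0.04). Their median of −0.11 had camera adjusted p = 0.0021, and adjusted p = 0.245 with an estimated correlation. Of the FoxO and starvation-associated genes, 3 of 21 rose and 14 fell (3 and 14 adjusted over the list alone), with Pdk4 at −1.07 ± 0.08 and Txnip rising at 0.86 ± 0.05. Their median of −0.35 had camera adjusted p = 0.000128, and adjusted p = 0.221 with an estimated correlation.

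Of the cholesterol synthesis genes at 6 h, 18 of 20 rose and 0 fell (18 and 1 adjusted over the list alone), with Hsd17b7 at 0.85 ± 0.05 and Idi1 at 0.78 ± 0.05. Their median of 0.33 had camera adjusted p = 5.52e-09, and adjusted p = 0.118 with an estimated correlation. Of the ribosome biogenesis genes, 19 of 27 rose and 2 fell (19 and 2 adjusted over the list alone), with Noc3l at 0.71 ± 0.06 and Polr1e, a subunit of the polymerase that makes ribosomal RNA, at 0.61 ± 0.08. Their median of 0.28 had camera adjusted p = 8.83e-05, and adjusted p = 0.151 with an estimated correlation. Of the endoplasmic reticulum chaperone and unfolded protein response genes, 16 of 18 rose and 1 fell (17 and 1 adjusted over the list alone), with Atf6 at 0.86 ± 0.04 and Creld2 at 0.75 ± 0.06. Their median of 0.32 had camera adjusted p = 1.8e-06, and adjusted p = 0.132 with an estimated correlation. Of the glycolysis and hypoxia-responsive genes, 16 of 26 rose and 4 fell (16 and 5 adjusted over the list alone), with hexokinase gene Hk2 at 1.68 ± 0.07 and Pfkp at 1.18 ± 0.07. Their median of 0.20 had camera adjusted p = 0.00299, and adjusted p = 0.258 with an estimated correlation. Of the osteochondrogenic genes, 8 of 17 rose and 1 fell (9 and 1 adjusted over the list alone), led by Acan, which encodes the cartilage proteoglycan aggrecan (2.38 ± 0.04), and by Enpp1 (1.21 ± 0.04). Their median of 0.21 had camera adjusted p = 0.00199, and adjusted p = 0.132 with an estimated correlation. Of the Wnt pathway genes, 2 of 23 rose and 9 fell (2 and 10 adjusted over the list alone), with Sfrp2 at −1.28 ± 0.08 and Fzd1 at −1.05 ± 0.06. Their median of −0.10 had camera adjusted p = 0.003, and adjusted p = 0.166 with an estimated correlation.

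The remaining 17 lists did not pass at 6 h, although single members changed. In the growth factor list 11 of 32 rose and 16 fell (11 and 16 adjusted over the list alone, median −0.24, camera adjusted p = 0.168): Nrg1 (−1.79 ± 0.06) and Edn1 (−1.64 ± 0.07) fell, whereas Igf1 (1.55 ± 0.09) and Fgf2 (1.54 ± 0.06) rose. In the inflammatory list 8 of 30 rose and 6 fell (10 and 7 adjusted over the list alone, median 0.04, camera adjusted p = 0.577), with Cxcl16 at 2.01 ± 0.05 and Il6 at −1.10 ± 0.10. In the NADPH oxidase and redox list 10 of 24 rose and 3 fell (10 and 3 adjusted over the list alone, median 0.08, camera adjusted p = 0.0832), with Nox1 at 1.41 ± 0.07 and Nox4 at −0.85 ± 0.05. Of the G protein signalling regulators 9 of 17 rose and 3 fell (9 and 3 adjusted over the list alone, median 0.19, camera adjusted p = 0.0989), with Rgs16 at 1.33 ± 0.08 and Rgs4 at −1.10 ± 0.10. Of the Notch pathway genes 4 of 16 rose and 5 fell (4 and 5 adjusted over the list alone, median −0.04, camera adjusted p = 0.282), with Jag1 at −1.51 ± 0.04. Of the calcium handling and ion channel genes 9 of 27 rose and 6 fell (9 and 7 adjusted over the list alone, median 0.01, camera adjusted p = 0.662), with Kcnn4 at 2.05 ± 0.09. In the renin-angiotensin list 0 of 13 rose and 4 fell (0 and 4 adjusted over the list alone, median −0.08, camera adjusted p = 0.12).

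Counts in the other lists, except the leukocyte and macrophage markers, went both ways at 6 h. Of the matrix proteases and their inhibitors 6 of 23 rose and 6 fell (6 and 6 adjusted over the list alone, median 0.00, camera adjusted p = 0.933, with a positive mean and an upward test against the negative median), with Plau at 1.52 ± 0.08 and Adamts9 at −1.38 ± 0.05. Of the extracellular matrix genes 7 of 28 rose and 6 fell (7 and 7 adjusted over the list alone, median 0.01, camera adjusted p = 0.845), with the hyaluronan synthase gene Has2 at 1.26 ± 0.10. Of the interferon-responsive genes 4 of 24 rose and 5 fell (4 and 5 adjusted over the list alone, median −0.06, camera adjusted p = 0.662, with a positive mean). Of the circadian clock genes 6 of 15 rose and 7 fell (6 and 7 adjusted over the list alone, median −0.02, camera adjusted p = 0.361), with Per3 at −1.18 ± 0.05. Of the TGF-beta and BMP signalling genes 8 of 24 rose and 10 fell (9 and 10 adjusted over the list alone, median −0.07, camera adjusted p = 0.355), with Fst at 1.41 ± 0.07. Of the ATF4 and amino acid supply genes 12 of 26 rose and 6 fell (15 and 7 adjusted over the list alone, median 0.15, camera adjusted p = 0.164), with Slc7a3 at 1.33 ± 0.06. Of the smooth muscle contractile genes 5 of 18 rose and 5 fell (5 and 5 adjusted over the list alone, median 0.02, camera adjusted p = 0.843), with Des at 0.48 ± 0.06. Markers of other cell types moved little as groups. Of the endothelial markers 2 of 13 rose and 2 fell (2 and 2 adjusted over the list alone, median 0.05, camera adjusted p = 0.755). Of the leukocyte and macrophage markers 1 of 16 rose and 0 fell (1 and 0 adjusted over the list alone, median −0.01, camera adjusted p = 0.951, with a positive mean and an upward test against the negative median). Of the fibroblast markers 2 of 14 rose and 4 fell (2 and 4 adjusted over the list alone, median −0.06, camera adjusted p = 0.144). Single markers did move, since Flt1, the gene of a receptor for vascular endothelial growth factor, rose (2.49 ± 0.05) and Pdgfra fell (−1.39 ± 0.06).

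**Figure D2:**
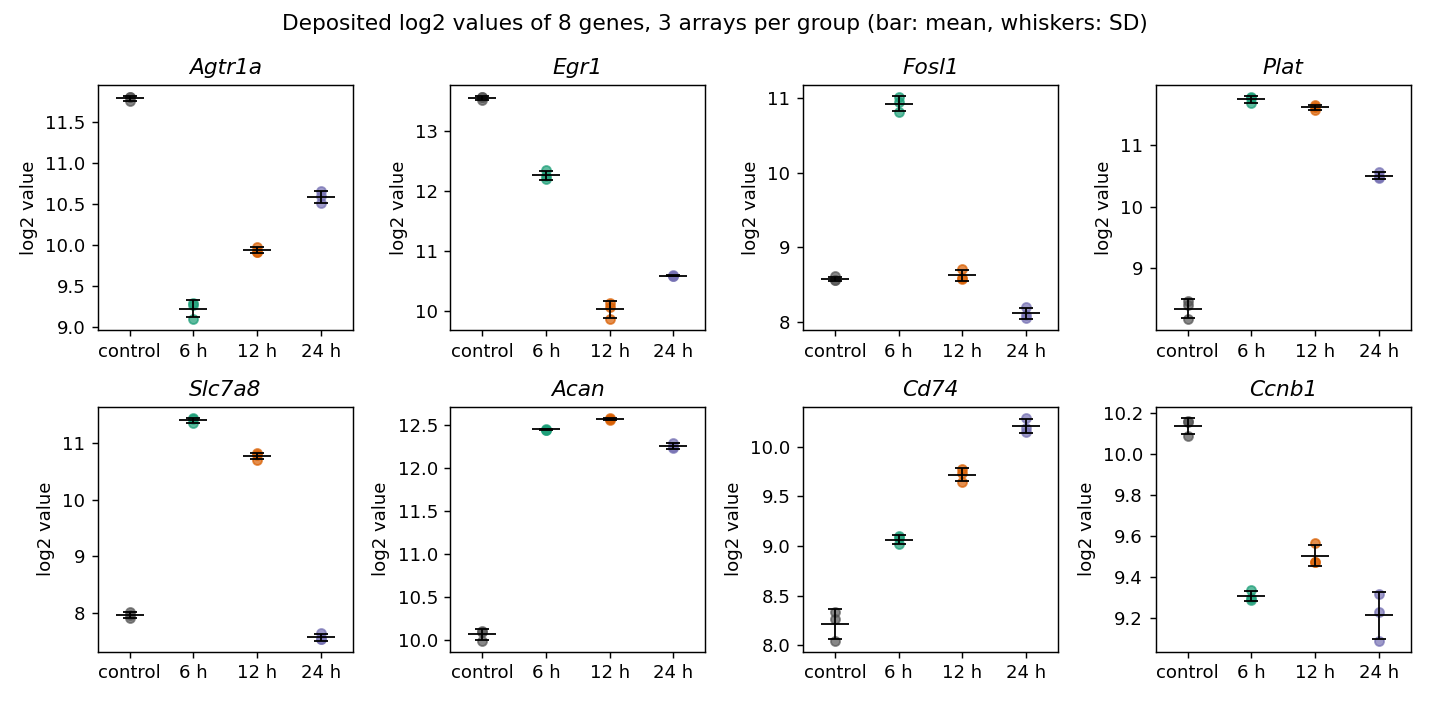
Deposited log2 values (y axis) of 8 genes in control and after 6, 12 and 24 h of Ang II (x axis); points are single arrays, the bar is the mean and the whiskers the SD of 3 arrays. Agtr1a is lowest at 6 h, Egr1 at 12 h, and Cd74 is higher at each later time, whereas Slc7a8 rises and then lies below control at 24 h; the y axes differ between panels.

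At 12 h the immediate-early genes showed the largest falls. Egr1 was 11.5-fold lower than in untreated cells (log2 change −3.53 ± 0.07, SE, n = 3 per group, adjusted p = 2.11e-11), Nr4a1 10-fold lower (−3.33 ± 0.11) and Fos 6.99-fold lower (−2.80 ± 0.10). They were followed by Ldb2 (−2.75 ± 0.13), Egr3 (−2.66 ± 0.09), Egr2 (−2.45 ± 0.08), the secreted Wnt modulator gene Sfrp2 (−2.16 ± 0.08), Dync1i1 (−2.10 ± 0.09), the endothelin gene Edn1 (−2.07 ± 0.07) and Pi15 (−2.06 ± 0.13). The largest rises were those of Plat (9.58-fold, log2 change 3.26 ± 0.07, adjusted p = 5.92e-11), Olr1 (3.08 ± 0.12) and Slc7a8 (2.81 ± 0.05). Next came Esm1 (2.72 ± 0.07), Ptprn (2.53 ± 0.06), Acan (2.50 ± 0.04), Ramp3 (2.45 ± 0.12), Fgl2 (2.35 ± 0.12), Gldn (2.31 ± 0.10) and Flt1 (2.28 ± 0.05). Agtr1a was 3.61-fold lower (−1.85 ± 0.06, adjusted p = 1.55e-09). Agtr1b had a log2 change of 0.36 ± 0.08 (adjusted p = 0.00577) and Agtr2 of −0.07 ± 0.13 (adjusted p = 0.779). In total 1932 genes were higher and 1923 lower (limma, adjusted p under 0.05), of which 285 and 251 differed by at least 1.5-fold. Of the 29 lists 14 passed camera, 5 upwards and 9 downwards. With an estimated correlation 0 passed (8 at an unadjusted p under 0.05), and 23 passed fry.

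Of the immediate-early and AP-1 factors, 1 of 23 rose and 17 fell (1 and 18 adjusted over the list alone) at 12 h. Their median of −1.19 had camera adjusted p = 3.36e-15, and adjusted p = 0.123 with an estimated correlation. The MAP kinase feedback regulators, higher at 6 h, were lower at 12 h: 1 of 17 rose and 10 fell (2 and 10 adjusted over the list alone), with Dusp5 at −1.44 ± 0.07 and Dusp1 at −0.80 ± 0.05. Their median of −0.33 had camera adjusted p = 0.00134, and adjusted p = 0.289 with an estimated correlation. Of the mitotic genes, 0 of 27 rose and 25 fell (0 and 25 adjusted over the list alone), with Ccnb1 at −0.63 ± 0.06 and Cdc20 at −0.51 ± 0.06. Their median of −0.35 had camera adjusted p = 9.97e-15, and adjusted p = 0.11 with an estimated correlation. Of the ribosome biogenesis genes, 0 of 27 rose and 13 fell (1 and 16 adjusted over the list alone), with Gnl3 at −0.60 ± 0.06 and Nob1 at −0.55 ± 0.04. Their median of −0.15 had camera adjusted p = 6.53e-06, and adjusted p = 0.132 with an estimated correlation. Of the cholesterol synthesis genes, 19 of 20 rose and 0 fell (19 and 0 adjusted over the list alone), with Hsd17b7 at 0.89 ± 0.05, Nsdhl at 0.84 ± 0.04 and Acat2 at 0.79 ± 0.05. Their median of 0.54 had camera adjusted p = 3.3e-16, and adjusted p = 0.0575 with an estimated correlation. Of the endoplasmic reticulum chaperone and unfolded protein response genes, 13 of 18 rose and 1 fell (15 and 1 adjusted over the list alone), with Atf6 at 0.98 ± 0.04 and Sdf2l1 at 0.51 ± 0.04. Their median of 0.19 had camera adjusted p = 2.1e-06, and adjusted p = 0.132 with an estimated correlation. Of the glycolysis and hypoxia-responsive genes, 15 of 26 rose and 3 fell (16 and 3 adjusted over the list alone), with the lactate transporter gene Slc16a3 at 1.20 ± 0.04 and Egln3 falling at −0.95 ± 0.06. Their median of 0.19 had camera adjusted p = 0.000266, and adjusted p = 0.166 with an estimated correlation.

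The smooth muscle contractile genes were higher at 12 h: 9 of 18 rose and 1 fell (10 and 1 adjusted over the list alone), with Des, which encodes desmin, at 0.63 ± 0.06 and Lmod1 at 0.29 ± 0.04. Their median of 0.11 had camera adjusted p = 0.000774, and adjusted p = 0.166 with an estimated correlation. Of the osteochondrogenic genes, 7 of 17 rose and 2 fell (9 and 2 adjusted over the list alone), with Acan as above, Mgp at 1.27 ± 0.07 and Enpp1 at 1.23 ± 0.04. Their median of 0.22 had camera adjusted p = 0.00294, and adjusted p = 0.132 with an estimated correlation. Of the circadian clock genes, 2 of 15 rose and 9 fell (3 and 9 adjusted over the list alone), with Bhlhe41 at −1.03 ± 0.06, Per3 at −1.01 ± 0.05 and Bmal1 rising at 0.73 ± 0.07. Their median of −0.56 had camera adjusted p = 0.000885, and adjusted p = 0.258 with an estimated correlation. Of the growth factors, 8 of 32 rose and 18 fell (9 and 18 adjusted over the list alone), with Bmp6 at −1.99 ± 0.07, Pdgfd at −1.95 ± 0.08 and Igf1 rising at 1.44 ± 0.09. Their median of −0.24 had camera adjusted p = 0.00426, and adjusted p = 0.333 with an estimated correlation. Of the Wnt pathway genes, 2 of 23 rose and 10 fell (2 and 10 adjusted over the list alone), with Wnt5a at −0.77 ± 0.08 and Ccn4 rising at 1.03 ± 0.04. Their median of −0.14 had camera adjusted p = 0.0166, and adjusted p = 0.258 with an estimated correlation. Among the 11 Wnt members at or above the median level alone, the call was lost (camera adjusted p = 0.056) while the median was −0.22.

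Of the cell cycle inhibitors, 3 of 16 rose and 7 fell (3 and 8 adjusted over the list alone), with Gadd45a at −0.44 ± 0.08 and Cdkn1b at −0.39 ± 0.04. Their median of −0.13 had camera adjusted p = 0.0369, and adjusted p = 0.426 with an estimated correlation. This call was lost without control replicate 2 (camera adjusted p = 0.0596, median −0.10), without Ang II 12 h replicate 1 (0.0712, median −0.09), without the array of narrowest spread in each Ang II group (0.0616, median −0.09) and among the 13 members at or above the median level (0.142, median −0.15). Of the FoxO and starvation-associated genes, 3 of 21 rose and 9 fell (3 and 12 adjusted over the list alone), with Txnip at 0.84 ± 0.05 and Irs1 at −0.53 ± 0.06. Their median of −0.20 had camera adjusted p = 0.023, and adjusted p = 0.426 with an estimated correlation. This call was lost without Ang II 12 h replicate 1 (camera adjusted p = 0.0763, median −0.15), without the array of narrowest spread in each Ang II group (0.0687, median −0.15) and among the 14 members at or above the median level (0.194, median −0.18).

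The other 15 lists did not pass at 12 h. Of the G1/S and DNA replication genes 4 of 34 rose and 6 fell (8 and 7 adjusted over the list alone, median −0.07, camera adjusted p = 0.447), with Tk1 falling at −0.57 ± 0.05 and Cdc6 rising at 0.41 ± 0.06. In the inflammatory list 3 of 30 rose and 9 fell (3 and 11 adjusted over the list alone, median −0.02, camera adjusted p = 0.298), with Vcam1 at −1.82 ± 0.10, Cxcl16 at 1.80 ± 0.05 and Ptgs2 at −1.19 ± 0.07. In the NADPH oxidase and redox list 6 of 24 rose and 6 fell (6 and 6 adjusted over the list alone, median 0.06, camera adjusted p = 0.416), with Nox1 at 1.61 ± 0.07 and Gclc at −0.83 ± 0.05. Of the ATF4 and amino acid supply genes 3 of 26 rose and 11 fell (5 and 11 adjusted over the list alone, median −0.04, camera adjusted p = 0.106), with Slc7a3 at 1.31 ± 0.06 and Chac1 at −0.94 ± 0.07. Of the TGF-beta and BMP signalling genes 5 of 24 rose and 11 fell (5 and 11 adjusted over the list alone, median −0.07, camera adjusted p = 0.134), with Id1 at −1.26 ± 0.08 and Fst at 1.24 ± 0.07. Of the calcium handling and ion channel genes 9 of 27 rose and 3 fell (9 and 3 adjusted over the list alone, median 0.05, camera adjusted p = 0.134), with Kcnn4 at 1.21 ± 0.09 and Cacna1c at −0.84 ± 0.06. Of the Notch pathway genes 3 of 16 rose and 5 fell (3 and 6 adjusted over the list alone, median −0.08, camera adjusted p = 0.142), with Hes1 at −1.12 ± 0.08. Of the G protein signalling regulators 5 of 17 rose and 2 fell (5 and 4 adjusted over the list alone, median 0.01, camera adjusted p = 0.358). In the renin-angiotensin list 2 of 13 rose and 3 fell (2 and 3 adjusted over the list alone, median −0.03, camera adjusted p = 0.662).

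In the extracellular matrix list at 12 h 7 of 28 rose and 6 fell (7 and 8 adjusted over the list alone, median −0.02, camera adjusted p = 0.907, with a positive mean), with Postn at 0.72 ± 0.04. In the protease list 5 of 23 rose and 7 fell (5 and 7 adjusted over the list alone, median −0.01, camera adjusted p = 0.686, with a positive mean), with Plau at 1.02 ± 0.08 and Adamts9 at −0.99 ± 0.05. Of the interferon-responsive genes 3 of 24 rose and 3 fell (3 and 3 adjusted over the list alone, median 0.00, camera adjusted p = 0.907), with Usp18 at 1.17 ± 0.21. Of the endothelial markers 3 of 13 rose and 2 fell (4 and 2 adjusted over the list alone, median 0.10, camera adjusted p = 0.355). Of the leukocyte and macrophage markers 1 of 16 rose and 0 fell (1 and 0 adjusted over the list alone, median −0.05, camera adjusted p = 0.974, with a positive mean and an upward test against the negative median). Of the fibroblast markers 2 of 14 rose and 7 fell (2 and 7 adjusted over the list alone, median −0.18, camera adjusted p = 0.112). The 1 leukocyte marker that rose was Cd74, the invariant chain that accompanies class II histocompatibility molecules (2.84-fold), and Pdgfra fell among the fibroblast markers (−1.24 ± 0.06).

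At 24 h Acan had the largest rise, at 4.57-fold (log2 change 2.19 ± 0.04, SE, n = 3 per group, adjusted p = 8.49e-11), followed by Plat (2.16 ± 0.07), Cd74 (1.99 ± 0.07) and Ptprn (1.89 ± 0.06). Next came Mustn1 (1.77 ± 0.06), the small heat shock protein gene Hspb6 (1.59 ± 0.07), Akap6 (1.54 ± 0.05), Itgb1bp2 (1.52 ± 0.07) and Fbxl22 (1.51 ± 0.06), besides Nipal4 (2.84-fold). Egr1 had the largest fall, at 7.79-fold (−2.96 ± 0.07, adjusted p = 2.27e-10). It was followed by Fos (−2.71 ± 0.10), Nr4a1 (−2.61 ± 0.11), Sfrp2 (−2.60 ± 0.08), Klf4 (−2.53 ± 0.07), Egr3 (−2.51 ± 0.09), Egr2 (−2.45 ± 0.08), the epiregulin gene Ereg (−2.45 ± 0.08), Aldh1a2 (−2.25 ± 0.15) and Pi15 (−2.21 ± 0.13). Agtr1a was still 2.3-fold lower than in control (−1.20 ± 0.06, adjusted p = 3.92e-08), and Agtr2 had a log2 change of −0.19 ± 0.13 (adjusted p = 0.286). Agtr1b had a log2 change of 0.28 ± 0.08 (adjusted p = 0.0243). This call was lost without control replicate 1 (adjusted p = 0.0984), without 24 h replicate 1 (0.0658) or replicate 3 (0.0858), after quantile normalization of the values once more (0.0901) and without moderation of the variance (0.0518).

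In total 2222 genes were higher and 2136 lower at 24 h (limma, adjusted p under 0.05), of which 230 and 332 differed by at least 1.5-fold. The higher genes were thus 51% of the changed genes, or 40.9% of those at 1.5-fold or more. With each array centred on its median, 3559 genes were higher and 1713 lower (67.5% higher), and the median over all genes then lay at 0.10 (log2). The 24 h arrays had a narrower spread of values over the tested genes than the control arrays, with interquartile ranges of 3.26 to 3.39 against 3.45 to 3.46. Of the 29 lists 13 passed camera, 3 upwards and 10 downwards. With an estimated correlation 0 passed (8 at an unadjusted p under 0.05), and 22 passed fry.

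The smooth muscle contractile genes were higher at 24 h: 17 of 18 rose and 0 fell (17 and 0 adjusted over the list alone), with Pln at 0.66 ± 0.04, Smtn at 0.66 ± 0.04 and Lmod1 at 0.59 ± 0.04. Their median of 0.32 had camera adjusted p = 1.49e-11, and adjusted p = 0.0575 with an estimated correlation. Genes of calcium handling and ion channels were also higher: 11 of 27 rose and 2 fell (14 and 2 adjusted over the list alone), with Kcnma1, the gene of the large-conductance potassium channel, at 0.90 ± 0.10 and Rcan2 at 0.74 ± 0.05. Their median of 0.20 had camera adjusted p = 0.00483, and adjusted p = 0.166 with an estimated correlation. Of the osteochondrogenic genes, 9 of 17 rose and 1 fell (10 and 1 adjusted over the list alone), with Enpp1 at 1.03 ± 0.04 and Col11a1 falling at −1.09 ± 0.05. Their median of 0.21 had camera adjusted p = 0.000774, and adjusted p = 0.123 with an estimated correlation. Both cell cycle lists were lower. Of the mitotic genes, 0 of 27 rose and 27 fell (0 and 27 adjusted over the list alone), with Ccnb1 at −0.93 ± 0.06 and Cdk1 at −0.78 ± 0.06. Their median of −0.57 had camera adjusted p = 4.84e-24, and adjusted p = 0.0575 with an estimated correlation. Of the G1/S and DNA replication genes, 1 of 34 rose and 27 fell (1 and 27 adjusted over the list alone), with Ccnd1, the cyclin gene that responds to growth factors, at −1.42 ± 0.05 and Gins1 at −0.88 ± 0.05. Their median of −0.44 had camera adjusted p = 3.3e-16, and adjusted p = 0.108 with an estimated correlation. Of the cell cycle inhibitors, 0 of 16 rose and 7 fell (0 and 8 adjusted over the list alone), with Ccng2 at −0.63 ± 0.07 and Cdkn2c at −0.62 ± 0.06. Their median of −0.11 had camera adjusted p = 0.00482, and adjusted p = 0.276 with an estimated correlation. That call was lost among the 13 members at or above the median level (camera adjusted p = 0.0921), whose median was −0.15.

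Of the immediate-early and AP-1 factors at 24 h, 2 of 23 rose and 19 fell (3 and 19 adjusted over the list alone). Their median of −0.78 had camera adjusted p = 8.23e-15, and adjusted p = 0.123 with an estimated correlation. Of the MAP kinase feedback regulators, 1 of 17 rose and 10 fell (1 and 11 adjusted over the list alone), with Dusp5 at −1.34 ± 0.07 and Spry2 at −0.70 ± 0.07. Their median of −0.27 had camera adjusted p = 0.000128, and adjusted p = 0.221 with an estimated correlation. Of the ribosome biogenesis genes, 0 of 27 rose and 14 fell (0 and 18 adjusted over the list alone), with Npm1 at −0.55 ± 0.05. Their median of −0.17 had camera adjusted p = 7.16e-08, and adjusted p = 0.11 with an estimated correlation. Of the growth factors, 8 of 32 rose and 15 fell (8 and 15 adjusted over the list alone), with Edn1 at −2.02 ± 0.07 and Bmp6 at −1.51 ± 0.07. Their median of −0.11 had camera adjusted p = 0.023, and adjusted p = 0.426 with an estimated correlation. Of the inflammatory genes, 3 of 30 rose and 10 fell (3 and 10 adjusted over the list alone), with the chemokine gene Cxcl12 at −1.14 ± 0.05 and Il6 at −0.92 ± 0.10. Their median of −0.02 had camera adjusted p = 0.033, and adjusted p = 0.151 with an estimated correlation. Of the FoxO and starvation-associated genes, 3 of 21 rose and 10 fell (3 and 11 adjusted over the list alone), with Igfbp5 rising at 0.92 ± 0.12 and Sesn3 falling at −0.90 ± 0.06. Their median of −0.18 had camera adjusted p = 0.0309, and adjusted p = 0.433 with an estimated correlation. Of the fibroblast markers, 3 of 14 rose and 6 fell (3 and 6 adjusted over the list alone), with Pdgfra at −1.15 ± 0.06 and Lum at −0.76 ± 0.06. Their median of −0.05 had camera adjusted p = 0.033, and adjusted p = 0.426 with an estimated correlation. Among genes at or above the median level, camera adjusted p was 0.0626 for 23 growth factors (median −0.13), 0.328 for 14 FoxO genes (−0.18) and 0.247 for 9 fibroblast markers (−0.22). The FoxO call was also lost after a further quantile normalization (0.0538) and with a trended, robust variance (0.0553), and the inflammatory call without 24 h replicate 1 (0.0643, median −0.03).

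The other 16 lists did not pass at 24 h. Of the cholesterol synthesis genes 4 of 20 rose and 8 fell (4 and 9 adjusted over the list alone, median −0.07, camera adjusted p = 0.0832), with Insig1 at −0.65 ± 0.04 and Tm7sf2 rising at 0.46 ± 0.04. Without 24 h replicate 3 the list passed (camera adjusted p = 0.0491). Of the endoplasmic reticulum chaperone and unfolded protein response genes 4 of 18 rose and 2 fell (5 and 2 adjusted over the list alone, median −0.03, camera adjusted p = 0.845, with a positive mean), with Atf6 at 0.40 ± 0.04. Of the glycolysis and hypoxia-responsive genes 9 of 26 rose and 6 fell (12 and 7 adjusted over the list alone, median 0.05, camera adjusted p = 0.653), with Adm at −0.83 ± 0.07 and Slc16a3 at 0.63 ± 0.04. Of the ATF4 and amino acid supply genes 11 of 26 rose and 5 fell (11 and 5 adjusted over the list alone, median 0.10, camera adjusted p = 0.168), with Slc7a3 at 0.93 ± 0.06. In the NADPH oxidase and redox list 3 of 24 rose and 9 fell (3 and 9 adjusted over the list alone, median 0.00, camera adjusted p = 0.121, with a negative mean and a downward test), with Gclc at −0.95 ± 0.05 and Hmox1 at −0.60 ± 0.07. Of the Notch pathway genes 4 of 16 rose and 3 fell (5 and 3 adjusted over the list alone, median 0.08, camera adjusted p = 0.907, with a negative mean), with Hes1 at −1.34 ± 0.08. Of the Wnt pathway genes 4 of 23 rose and 7 fell (4 and 7 adjusted over the list alone, median 0.07, camera adjusted p = 0.662, with a negative mean and a downward test). Of the circadian clock genes 4 of 15 rose and 6 fell (4 and 6 adjusted over the list alone, median 0.03, camera adjusted p = 0.476, with a negative mean and a downward test), with Bmal1 falling at −0.68 ± 0.07 and Dbp rising at 0.54 ± 0.06.

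Of the TGF-beta and BMP signalling genes at 24 h 8 of 24 rose and 7 fell (8 and 8 adjusted over the list alone, median −0.05, camera adjusted p = 0.686), with Smad6 at −0.88 ± 0.05 and Id1 at −0.86 ± 0.08. In the extracellular matrix list 8 of 28 rose and 6 fell (8 and 6 adjusted over the list alone, median −0.01, camera adjusted p = 0.748, with a positive mean), with the periostin gene Postn at 1.01 ± 0.04 and Col3a1 at −0.35 ± 0.04. In the protease list 7 of 23 rose and 5 fell (9 and 6 adjusted over the list alone, median 0.08, camera adjusted p = 0.801), with Adamts5 at −1.16 ± 0.08. Of the interferon-responsive genes 1 of 24 rose and 7 fell (1 and 7 adjusted over the list alone, median −0.02, camera adjusted p = 0.308), with Ifi44 at −0.63 ± 0.10. In the renin-angiotensin list 5 of 13 rose and 3 fell (6 and 3 adjusted over the list alone, median 0.15, camera adjusted p = 0.919, with a negative mean). Of the G protein signalling regulators 4 of 17 rose and 3 fell (5 and 3 adjusted over the list alone, median 0.08, camera adjusted p = 0.649), with Rgs4 at 0.76 ± 0.10. Of the endothelial markers 5 of 13 rose and 1 fell (5 and 1 adjusted over the list alone, median 0.09, camera adjusted p = 0.0912), with Flt1 at 1.06 ± 0.05 and Tek at −0.91 ± 0.09. The list passed without control replicate 1 (camera adjusted p = 0.0495) and among genes at or above the median level, which left 2 of the markers (0.0132). Of the leukocyte and macrophage markers 1 of 16 rose and 1 fell (1 and 1 adjusted over the list alone, median 0.06, camera adjusted p = 0.71), the rise being that of Cd74 and the fall that of Cd14 (−1.01 ± 0.08).

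**Figure D3:**
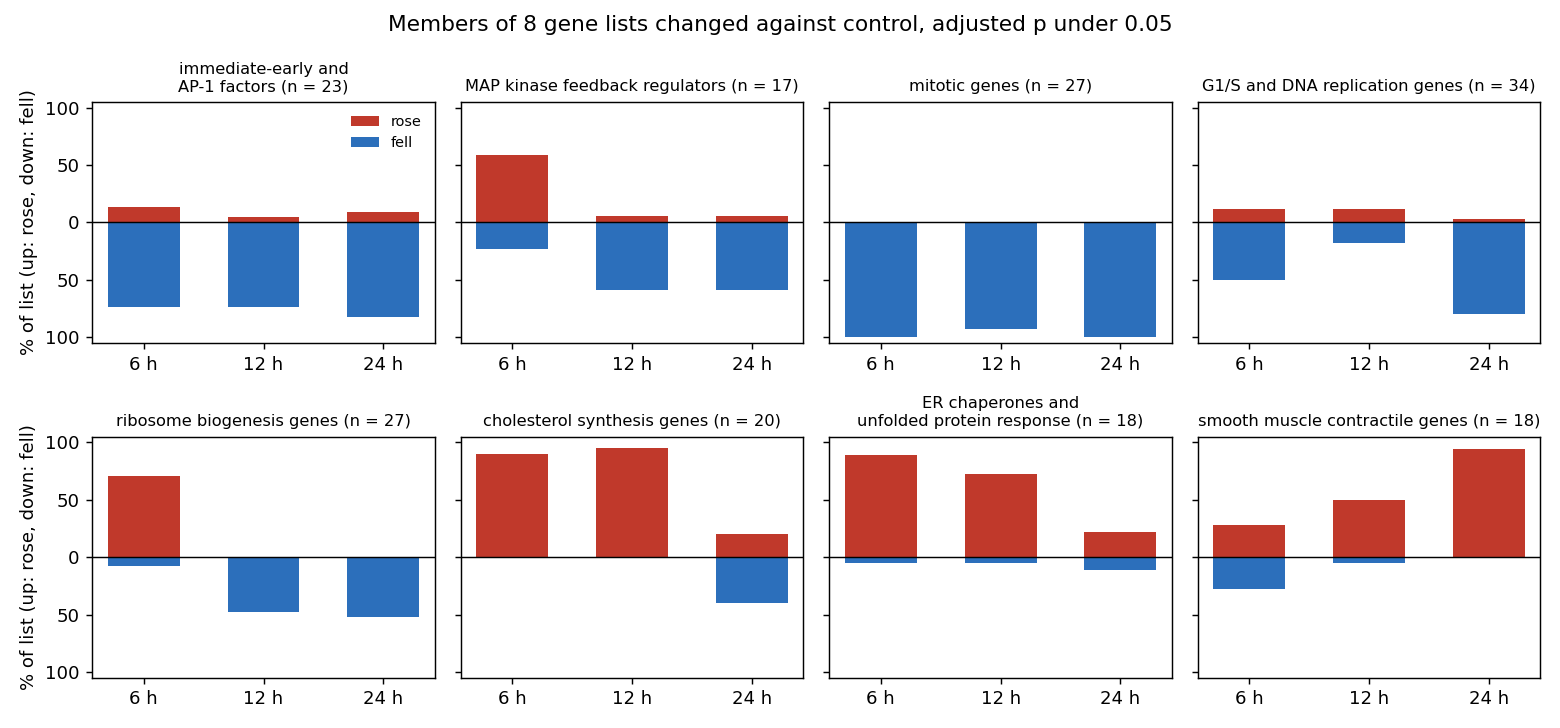
Share of the measured members (n in each panel title) of 8 gene lists that rose (bars above 0) or fell (bars below 0) against control at 6, 12 and 24 h of Ang II (x axis), in percent (y axis), at a limma adjusted p under 0.05. Mitotic genes fell at each time, cholesterol synthesis genes rose at 6 h and 12 h (18 and 19 of 20), and 17 of 18 contractile genes rose at 24 h.

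Between 6 h and 12 h the early transcription factor genes fell. The largest falls were those of Fosl1 (log2 change −2.30 ± 0.06, SE, n = 3 per group, adjusted p = 1.95e-09), Egr1 (−2.24 ± 0.07), the orphan nuclear receptor gene Nr4a3 (−2.16 ± 0.08), Plk3 (−2.06 ± 0.09) and the phosphatase gene Dusp5 (−2.05 ± 0.07). The largest rises were those of Rab39a (1.54 ± 0.07), Mllt3 (1.43 ± 0.09), Fgf16 (1.40 ± 0.10), the arginine transporter gene Slc7a2 (1.38 ± 0.05) and Sesn3 (1.34 ± 0.06). In total 1894 genes were higher and 2016 lower at 12 h than at 6 h (limma, adjusted p under 0.05), of which 196 and 213 differed by at least 1.5-fold. The lists were compared between times only after the comparisons with control had been seen. From 6 h to 12 h 12 of the 29 lists passed camera, 6 in each direction, and 1 with an estimated correlation (4 at an unadjusted p under 0.05). Of the ribosome biogenesis genes, 0 of 27 rose and 24 fell (0 and 25 adjusted over the list alone). Their median of −0.42 had camera adjusted p = 1.22e-16, and adjusted p = 0.0395 with an estimated correlation. Of the MAP kinase feedback regulators, 2 of 17 rose and 12 fell (2 and 13 adjusted over the list alone). Their median of −0.52 had camera adjusted p = 1.47e-08, and adjusted p = 0.129 with an estimated correlation. Of the immediate-early and AP-1 factors, 1 of 23 rose and 16 fell (1 and 17 adjusted over the list alone). Their median of −0.47 had camera adjusted p = 1.68e-09, and adjusted p = 0.245 with an estimated correlation. Mitotic genes rose in part between these times: 13 of 27 rose and 0 fell (15 and 0 adjusted over the list alone). Their median of 0.16 had camera adjusted p = 1.09e-05, and adjusted p = 0.302 with an estimated correlation. Of the G1/S and DNA replication genes, 16 of 34 rose and 2 fell (17 and 5 adjusted over the list alone). Their median of 0.12 had camera adjusted p = 0.000949, and adjusted p = 0.389 with an estimated correlation.

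Of the ATF4 and amino acid supply genes between 6 h and 12 h, 3 of 26 rose and 12 fell (3 and 13 adjusted over the list alone). Their median of −0.13 had camera adjusted p = 0.000273, and adjusted p = 0.298 with an estimated correlation. Of the inflammatory genes, 2 of 30 rose and 10 fell (2 and 12 adjusted over the list alone). Their median of −0.09 had camera adjusted p = 0.017, and adjusted p = 0.141 with an estimated correlation. Of the circadian clock genes, 3 of 15 rose and 7 fell (3 and 7 adjusted over the list alone). Their median of −0.15 had camera adjusted p = 0.0465, and adjusted p = 0.532 with an estimated correlation. Of the cell cycle inhibitors, 9 of 16 rose and 2 fell (9 and 2 adjusted over the list alone). Their median of 0.15 had camera adjusted p = 0.00188, and adjusted p = 0.298 with an estimated correlation. Of the FoxO and starvation-associated genes, 8 of 21 rose and 0 fell (8 and 0 adjusted over the list alone). Their median of 0.07 had camera adjusted p = 0.00171, and adjusted p = 0.366 with an estimated correlation. Of the cholesterol synthesis genes, 9 of 20 rose and 1 fell (10 and 1 adjusted over the list alone). Their median of 0.12 had camera adjusted p = 0.00437, and adjusted p = 0.386 with an estimated correlation. Of the contractile genes, 4 of 18 rose and 0 fell (4 and 0 adjusted over the list alone). Their median of 0.06 had camera adjusted p = 0.00947, and adjusted p = 0.33 with an estimated correlation.

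The largest fall between 12 h and 24 h was that of Slc7a8, which was 9.22-fold lower at 24 h than at 12 h (log2 change −3.20 ± 0.05, SE, n = 3 per group, adjusted p = 1.02e-11), and Olr1 (−2.32 ± 0.12), Ramp3 (−2.29 ± 0.12), Serpinb2 (−1.97 ± 0.19) and Esm1 (−1.91 ± 0.07) followed. The largest rises were those of the growth factor gene Pdgfd (1.49 ± 0.08), Cdo1 (1.47 ± 0.10), the natriuretic peptide clearance receptor gene Npr3 (1.35 ± 0.08), the clock output gene Dbp (1.34 ± 0.06) and Rai2 (1.30 ± 0.06). In total 2028 genes were higher and 1955 lower at 24 h than at 12 h (limma, adjusted p under 0.05; 50.9% higher), of which 133 and 220 differed by at least 1.5-fold (37.7% higher). With each array centred on its median the counts were 2957 higher and 1725 lower (63.2% higher).

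From 12 h to 24 h 9 of the 29 lists passed camera, 3 upwards and 6 downwards, and 1 with an estimated correlation (5 at an unadjusted p under 0.05). Of the cholesterol synthesis genes, 0 of 20 rose and 18 fell (0 and 18 adjusted over the list alone). Their median of −0.64 had camera adjusted p = 6.38e-20, and adjusted p = 0.0395 with an estimated correlation. Of the mitotic genes, 0 of 27 rose and 21 fell (0 and 22 adjusted over the list alone). Their median of −0.27 had camera adjusted p = 8.52e-11, and adjusted p = 0.141 with an estimated correlation. Of the G1/S and DNA replication genes, 0 of 34 rose and 29 fell (1 and 29 adjusted over the list alone). Their median of −0.31 had camera adjusted p = 1.54e-16, and adjusted p = 0.101 with an estimated correlation. Of the contractile genes, 12 of 18 rose and 0 fell (14 and 0 adjusted over the list alone). Their median of 0.24 had camera adjusted p = 2.65e-06, and adjusted p = 0.129 with an estimated correlation. Of the endoplasmic reticulum chaperone and unfolded protein response genes, 1 of 18 rose and 11 fell (1 and 12 adjusted over the list alone). Their median of −0.17 had camera adjusted p = 8.03e-07, and adjusted p = 0.141 with an estimated correlation. Of the ATF4 and amino acid supply genes, 14 of 26 rose and 2 fell (14 and 3 adjusted over the list alone). Their median of 0.19 had camera adjusted p = 0.000253, and adjusted p = 0.298 with an estimated correlation. Of the circadian clock genes, 8 of 15 rose and 3 fell (9 and 3 adjusted over the list alone). Their median of 0.38 had camera adjusted p = 0.0112, and adjusted p = 0.413 with an estimated correlation. Of the glycolysis and hypoxia-responsive genes, 1 of 26 rose and 11 fell (1 and 13 adjusted over the list alone). Their median of −0.08 had camera adjusted p = 0.00122, and adjusted p = 0.298 with an estimated correlation. Of the NADPH oxidase and redox genes, 3 of 24 rose and 8 fell (4 and 8 adjusted over the list alone). Their median of −0.07 had camera adjusted p = 0.00527, and adjusted p = 0.302 with an estimated correlation.

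Changes at the 3 times overlapped. Against control 720 genes were higher and 818 lower at all 3 times, among them Plat, Acan and Ptprn upwards and Agtr1a, Sfrp2, Pi15 and Egr1 downwards. At both 6 h and 24 h 918 genes were higher and 1060 lower. Independent lists of these sizes would share 414 and 366. The 3 control arrays cannot be split, so part of the excess may come from their sharing. The log2 changes at 6 h and 24 h had a correlation of 0.431 across genes, which are not independent replicates, and a covariance of 0.038, against 0.0031 from the shared controls with no effect.

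Other genes changed in opposite directions at 6 h and 24 h: 329 were higher at 6 h and lower at 24 h, and 240 the reverse, each with a passing difference between these times. At 6 h and then at 24 h the log2 change against control was 3.45 ± 0.05 and −0.39 ± 0.05 in Slc7a8, 2.35 ± 0.06 and −0.46 ± 0.06 in Fosl1, and 2.02 ± 0.05 and −0.44 ± 0.05 in the uridine phosphorylase gene Upp1. It was 1.76 ± 0.10 and −0.51 ± 0.10 in Dhrs9 and 1.57 ± 0.06 and −0.65 ± 0.06 in Trib1. In the reverse direction it was −1.31 ± 0.07 and 1.13 ± 0.07 in Rab39a, −1.29 ± 0.09 and 0.63 ± 0.09 in Popdc3, −1.10 ± 0.10 and 0.76 ± 0.10 in Rgs4, −1.32 ± 0.06 and 0.54 ± 0.06 in Dbp, and −1.42 ± 0.05 and 0.41 ± 0.05 in Slc7a2. At a change of at least 1.5-fold at both times, 18 genes were opposite.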

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

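The comparisons of gene lists between times were chosen after the changes against control had been seen, and the tests of single genes between times were planned.

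The effects at 6 h and 24 h differed in sign, with a passing test of the difference, in 569 genes, among them Slc7a8, Fosl1 and Upp1 (higher, then lower) and Rab39a, Rgs4 and Dbp (lower, then higher). Of 100 regroupings of the 12 arrays, 1, the real one, gave as many, and the highest of the others gave 0. The other regroupings also gave 0 genes in the median on the F test. The comparison with them therefore shows that the groups differ and does not test the change of sign itself.

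Genes of 2 lists also passed against control in opposite directions. The MAP kinase feedback regulators, with Dusp6 and Dusp10 high at 6 h and Dusp5 and Spry2 low at 24 h, had a median log2 change of −0.52 from 6 h to 12 h and of −0.49 from 6 h to 24 h. The ribosome biogenesis genes, with Noc3l high at 6 h and Npm1 low at 24 h, had a median of −0.42 from 6 h to 12 h and of −0.47 from 6 h to 24 h. Against control the calls of both lists were lost with an estimated correlation. Between times, the ribosome biogenesis genes passed with it (adjusted p = 0.0395 from 6 h to 12 h and 0.0484 from 6 h to 24 h) and the MAP kinase feedback regulators did not (adjusted p = 0.129 and 0.245).

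Probe sets without a single gene name entered the comparisons of the report only in the alternative that tests all probe sets. Of 13904 such probe sets, 2156 changed against control at 6 h (961 higher and 1195 lower), 1701 at 12 h (723 and 978) and 2169 at 24 h (961 and 1208) (limma, adjusted p under 0.05). What these probe sets measure was not analysed here.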

How the results depend on the processing

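The fit without the array of narrowest spread in each Ang II group and the test of those arrays were chosen after seeing the data. No call of a named gene or list reversed. Which direction held more genes did switch between fits, in each comparison. At 24 h 2222 genes were higher and 2136 lower in the main fit, and 1955 and 1666 without 24 h replicate 2. The lower genes were more without 24 h replicate 1 (1863 higher and 2277 lower) and among genes at or above the median level (1775 and 2096). Leaving out each array in turn gave 2279 to 2772 higher and 2120 to 2528 lower genes at 6 h, 1536 to 1988 and 1552 to 1976 at 12 h, 1719 to 2270 and 1666 to 2277 at 24 h, 1539 to 1966 and 1562 to 2082 from 6 h to 12 h, and 1536 to 2044 and 1520 to 2121 from 12 h to 24 h. The F test then called 6895 to 7371 genes and 391 to 589 genes were opposite, and 12, 12 to 14 and 12 to 14 lists passed at the 3 times. With a minimum of 1.5-fold, which lowers counts by construction, 468 genes were higher and 529 lower at 6 h, 285 and 251 at 12 h, 230 and 332 at 24 h, 196 and 213 from 6 h to 12 h, and 133 and 220 from 12 h to 24 h, and 18 were opposite. Testing all probe sets singly gave 3333 lower at 24 h, over more features. Median centring gave 3559 higher genes at 24 h, and the cause was not tested. With an estimated correlation 0, 0 and 0 lists passed camera at 6, 12 and 24 h (6, 8 and 8 at an unadjusted p under 0.05), and 26, 23 and 22 passed fry, which does not compare a list with other genes. Of 408 calls of named genes, 112 were lost under 1 or more alternatives, all 112 under the minimum of 1.5-fold. Of 39 list calls, 39 were lost with the estimated correlation. The labels do not say whether the replicate numbers pair the arrays, and the values do not settle it. Over 18 pairs of the same number, the correlation of deviations from the group means was −0.10 to 0.30 (median 0.026, 3 over 0.1). Yet 7 of 12 arrays matched best with their own number in another group. With the replicate block 2631 genes were higher and 2428 lower at 6 h, 1864 and 1867 at 12 h, 2244 and 2051 at 24 h, 7378 differed among the groups and 525 were opposite, and no call of a named gene or list changed. In the 3 arrays of narrowest spread in their group the deviation from the group mean correlated with gene level at −0.25 or below across genes, so genes lower than most lay above their group mean there. Without them 2590 genes were higher and 2258 lower at 6 h, 1834 and 1666 at 12 h, and 2010 and 1674 at 24 h. Signal over background was not given, so which dim genes lie near the floor stays unknown.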

Other observations

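The sarcomere and class II lists with all their tests, the tests of the between-array normalization and of single control arrays on the immediate-early genes, and the count of mitotic genes that rose from 6 h to 12 h were chosen after the results they bear on had been seen, or after related values had. So were the mitotic gene values from 6 h to 24 h. The other tests were recorded as written down in advance. The fit that showed these patterns also gave the MAP kinase feedback, leukocyte and mitotic list medians against control. The tests that rest on those lists are therefore not independent predictions.

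Genes of the striated muscle sarcomere, the contractile unit of skeletal and heart muscle, rose at 24 h in these vascular smooth muscle cells. Of 36 measured genes of a textbook list, 19 rose and 1 fell (median log2 change 0.25, camera p = 2.92e-08, p = 0.00134 with an estimated correlation). Myosin heavy chain genes Myh1 (1.31 ± 0.05) and Myh2 (1.16 ± 0.07), skeletal actin Acta1 (0.97 ± 0.04) and troponin gene Tnnc1 (0.72 ± 0.07) rose most clearly, and Actn2 fell (−0.27 ± 0.09). The list also holds Casq2 and Ckm, which encode calsequestrin and creatine kinase rather than contractile proteins. Both are among the genes that rose, with log2 changes of 0.45 and 0.39. At 6 h 5 rose and 0 fell, at 12 h 6 rose and 1 fell, and the list passed camera at neither time. These p-values and those of the class II genes below are not adjusted for the several lists and times looked at. None of these genes was on the contractile list fixed in advance. The myosin heavy chain genes are related in sequence, so their probe sets may share signal, and 27 of the 36 genes lie below the median level of all genes. Acta1 already lay at 13.12 (log2) in control, and whether its probe set measures skeletal actin alone was not tested.

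The narrower spread of the 24 h arrays could lift dim genes, since the median log2 change at 24 h was 0.09 over all genes below the median level and −0.01 over those at or above it. It does not account for the rise of the sarcomere list, since 8 of the 9 members at or above that level rose and 0 fell (median 0.57, camera p = 1.33e-07, p = 0.000674 with an estimated correlation). Casq2 and Ckm are among these 8. Of the 27 dimmer members 11 rose and 1 fell (median 0.19, camera p = 0.00013 against other dim genes, p = 0.033 with an estimated correlation).

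Genes of class II antigen presentation were higher at 24 h. Of 9 measured genes 5 rose and 0 fell at 24 h (median 0.19, camera p = 0.00363, p = 0.0165 with an estimated correlation), with RT1-Da at 0.73 ± 0.08, RT1-Ba at 0.67 ± 0.15 and Ciita, the activator of these genes, at 0.27 ± 0.07. At 12 h 4 of 9 rose (camera p = 0.0352, p = 0.06 with an estimated correlation), and at 6 h 1 rose, which was Ciita. Ciita was highest at 6 h (0.64 ± 0.07) and lower at 12 h (0.37 ± 0.07), a course unlike that of RT1-Da (0.18 ± 0.08, not passed, and 0.54 ± 0.08). Below the median level of all genes lie 8 of the 9, with a median of 0.21 at 24 h. Cd74 itself rose at each time, with a log2 change of 0.85 ± 0.07 at 6 h and 1.99 ± 0.07 at 24 h.

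The values argue against leukocytes in the cultures as the source of Cd74, as far as dim markers can show: the median of the leukocyte and macrophage list without Cd74 was 0.06 at 24 h, and the leukocyte genes Ptprc (−0.02 ± 0.09), Tyrobp (0.07 ± 0.09) and Laptm5 (−0.07 ± 0.08) did not pass. Cd14 fell (−1.01 ± 0.08), but it lay at 8.22 in control, well above these genes. Whether its signal reports leukocytes was not tested. Of the 16 markers 1 reaches the median level of all genes, and Ptprc (5.49), Laptm5 (5.48) and Tyrobp (6.43) lay below the array medians in control. No 1 array carries the rise, since the log2 change stayed at 1.91 or above without any 1 array of control or 24 h. Induction of the class II genes as a group, with 5 of 9 rising, is consistent with the rise at 24 h, as a hypothesis, though at 6 h Cd74 rose with 1 of them. Whether Ang II or time in culture raised them stays open.

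Immediate-early genes such as Egr1, Fos and Nr4a1 were lower at 12 h and 24 h than in untreated cells. With the values quantile normalized again or median centred, the list median at 12 h was −1.18 or lower. The array medians already lay at 7.22 to 7.32, so a further scaling could hardly have moved this list. It therefore cannot show whether normalization played a part. The authors' own normalization could not be tested, because scanner files were not used. No 1 control array accounts for the lower values, since the list median at 12 h was −1.13 or lower without any of them. A stimulus to the untreated cells at harvest would raise these genes in control, and it predicts lower MAP kinase feedback genes at 24 h, whose median was −0.27. A refractory state after Ang II predicts the same sign, so both cannot be told apart without untreated cells of matched times.

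Mitotic genes such as Ccnb1 and Top2a were lower at 6 h and 12 h than in untreated cells. Under both further scalings the list median at 6 h was −0.54 or lower. Because the array medians were already alike, this cannot show whether normalization played a part. The authors' own normalization could not be tested here either. A steady loss of cycling cells with time without serum predicted a median from 12 h to 24 h of 0 or below, and the median was −0.27. Values looked up afterwards bear on it too. From 6 h to 12 h 13 of 27 genes rose while 0 fell, where a steady loss predicts no rise. From 6 h to 24 h 3 rose and 6 fell, with a median of only −0.07 (camera adjusted p = 0.066). An uneven loss, and an effect of Ang II, which the design names, both stay open because time and treatment move together.

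The count of genes that differed among the 4 groups was 7465, and 1 of 100 regroupings of the 12 arrays, the real one, gave as many, with 1045 as the highest of the others. A count that large thus did not arise when arrays were regrouped at random. Chance differences between the cultures of the groups are not excluded, since the labels do not say that the arrays came from separate cultures. The lists that passed camera numbered 12 at 6 h, 14 at 12 h and 13 at 24 h. As many passed in 2, 1 and 1 of the 100 regroupings, the real one included. The highest of the others were 13, 12 and 11. Totals as large thus came in a share under 0.05 of the regroupings, although at 6 h 1 other regrouping passed more lists than the real one. This concerns the totals and clears no single list of chance. The other regroupings passed 6 lists in the median at each time, where 0 genes in the median differed among the groups, so single lists past the preset-correlation test are not rare when groups are mixed. Mixed groups can keep part of the real differences, so this gives no rate of false calls. For the pairs of groups the 10 splits of 6 arrays are too few for a share under 0.05. The real splits changed 5191 genes at 6 h, 3855 at 12 h, 4358 at 24 h, 3910 from 6 h to 12 h and 3983 from 12 h to 24 h. In each of these 5 comparisons 1 split, the real one, gave as many, and the highest of the others was 0.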
